A study of Arabidopsis thaliana with 8 samples.

How the data were processed

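RNA-seq of whole seedlings, 12 days old, of Arabidopsis thaliana was analysed in 8 samples of 3 genotypes: WT (n = 2), 35S:SPCHΔ49 (n = 3) and 35S:SPCHΔ49 in basl-2 (n = 3). Seedlings were grown on MS medium in long days without treatment, per the labels' protocols. Total RNA was taken with a Qiagen plant kit and made into libraries with an Illumina TruSeq kit, per the labels' protocols. Reads were trimmed with Trimmomatic 0.38 and transcripts were quantified with kallisto 0.44.0, and sleuth is named without a version, per the submitters' processing notes. The genome build and annotation, how transcripts were summed to genes and how the listed genes were selected are not given in the sources used here.

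The deposited values are one signal per gene and sample, which the authors named TPM, per the file headers. They are treated here as a signal and not as plain TPM, since their totals differ between samples (852202 to 1075376), which TPM over all transcripts would not, while the medians are nearly equal (12.3 to 13.6). Some totals exceed the fixed sum of TPM, which selecting genes alone could not bring about. The authors therefore rescaled the values, and may also have selected genes, by a step that no source states. The design fixed beforehand had assumed TPM, and its test applies to this unit too. No counts were used, so no count model was run, and the depth of each library, which would set how precise low values are, is unknown. The table of the whole series and the files per sample agreed to within 4.96e-06. All 18855 listed genes reached a signal of 1 in every library of at least 1 genotype, which makes the list itself a filtered one.

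Differences were tested with limma 3.58.1 in R 4.3.3 on log2(signal + 1), with 1 mean per genotype over all 8 samples, moderated variances with an intensity trend, and Benjamini-Hochberg adjustment over all genes of a comparison at a threshold of 0.05. A filter of a signal of at least 1 in at least 2 samples was set and removed 0 genes. Fold changes carry the pseudocount of 1 and understate low genes. A signal of exactly 0 can be a failed estimate, and such genes are reported as listed at 0 with each library's value. The fit was tested on simulated data made from 18725, 18715 and 18721 genes, with 100 genes changed by 2-fold and 100 by 4-fold. It found 54% and 88% of them for SPCHΔ49 against WT, 59% and 84% for SPCHΔ49 basl-2 against WT, and 61% and 90% for SPCHΔ49 basl-2 against SPCHΔ49. In the same order, 13 of 155, 14 of 157 and 8 of 159 calls were false. The changed genes were drawn only from those with a WT signal above about 5, with noise independent between genes. Recovery at lower signals was therefore not tested. The median residual SD on the log2 scale was 0.21 for genes with a mean signal under 5, and between 0.16 and 0.18 above that.

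A total of 20 gene lists with 349 members, of which 315 were listed, was fixed before the data were examined: stomatal lineage regulators, guard cell function, cell cycle and DNA replication, trichome development, cuticle and epidermal wax, photosynthesis, root markers, vascular markers, abscisic acid and dehydration response, salicylic acid defence, jasmonate and ethylene defence, glucosinolates, flavonoids and anthocyanins, auxin, brassinosteroids, cell wall loosening, circadian clock, seed storage, senescence and reference genes. They were tested with limma's camera at a preset correlation of 0.01, which compares a list with the other genes, with adjustment over the 20 lists of a comparison. With a correlation estimated from the residuals 0 lists passed camera in any comparison, with 4, 2 and 3 lists at an unadjusted p under 0.05, while limma's fry passed 10, 10 and 4. The lists on root endodermis and suberin, on root stele and transport, and on sugar starvation were added after the data were examined.

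The rule for the genes the text may name was also fixed before the data were examined. It takes SPCH and BASL. It takes the 10 largest increases and the 10 largest decreases per comparison among genes past the threshold whose samples do not overlap and whose mean is at least 5 in the higher group. It takes up to 2 rising and 2 falling members of each list with the lowest adjusted p, and any lineage regulator past the threshold. Of those genes, 79, 73 and 39 per comparison, the text gives a part, and names others beside them only as list members. Gene names came from the deposited files where these gave one (10306 genes), otherwise from the reference annotation, and for list members from the lists. The reference annotation matched 18754 identifiers, and the other 101 are organelle genes. Members of near-identical families (RBCS, LHCB, PDF1.2, MLP) share reads and are uncertain one by one. Whether the library kit's strand information was used is not given in the sources used here, so overlapping and antisense genes are uncertain too.

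The design, the tests and most alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5, quantile normalization, TMM scaling, a rescaling that left out 122 genes (SPCH, organelle genes and the 20 most abundant), only the groups compared in the model, no intensity trend, sample quality weights, the replicate number as a block, a fold of at least 2, other list tests, and each sample left out in turn. A covariate for salicylic acid genes, the removal of genes at the level of root markers, TMM scaling for the list tests and the lineage list without SPCH and BASL were added after the data were examined. The removed genes were those whose WT mean was over 10 times both overexpressor means in these data. Genes lowered less, such as PHO1, were kept, so the removal cannot show how many calls root content accounts for. Where a WT sample was left out, the remaining one was assumed to vary like the other groups. The planned count models were not run because no counts were used here. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.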

Results

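Polyadenylated RNA of whole seedlings of Arabidopsis thaliana, 12 days old, was profiled in 3 genotypes. The wild type (WT) was represented by 2 samples. The line SPCHΔ49, with 3 samples, carried a truncated form of SPEECHLESS (SPCH) behind the 35S promoter, and SPCHΔ49 basl-2, also with 3 samples, carried it in the basl-2 mutant. SPCH is the basic helix-loop-helix transcription factor that starts the stomatal lineage, and the truncated form lacks the part through which MAP kinases mark the protein for degradation. BASL is a polarity protein of the asymmetric divisions in that lineage. Both overexpressing lines form an excess of stomatal lineage cells according to the series' design, and the comparisons address which genes accompany that excess. The deposited signal of 18855 genes summed to between 852202 and 1075376 per library, with a median gene between 12.3 and 13.6. These totals are not read numbers, so the sequencing depth is unknown and no counting error can be given. Between replicates, 1.61% of the genes differed by at least 2-fold in WT, and up to 9.85% did between SPCHΔ49 basl-2 replicates 2 and 3. The labels do not say that the replicates were grown separately, so p-values measure only the spread between these samples.

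SPCH (AT5G53210) had a signal of 6.92 ± 1.80 (SD, n = 2) in WT, 2491 ± 136 (SD, n = 3) in SPCHΔ49 and 407.2 ± 74.9 (SD, n = 3) in SPCHΔ49 basl-2. All 3 libraries of each overexpressor lay above both WT libraries, as the labels require. A value per gene does not separate transgene from endogenous transcript. BASL (AT5G60880) stood at 3.43 ± 0.127 in WT (n = 2), at 51.0 ± 13.6 in SPCHΔ49 (n = 3) and at 2.74 ± 0.581 in SPCHΔ49 basl-2 (n = 3). The log2 fold change of BASL was 3.52 (SE 0.25) in SPCHΔ49 against WT, with a limma adjusted p of 9.02e-05. Between SPCHΔ49 basl-2 and WT it was -0.26, with an adjusted p of 0.451, so no difference was detected. Transcript may still be made from the basl-2 allele, and the level of BASL therefore does not test the label of the mutant. Fold changes here and below are on the log2(signal + 1) scale, which understates the change of genes with low signal.

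**Figure D1:**
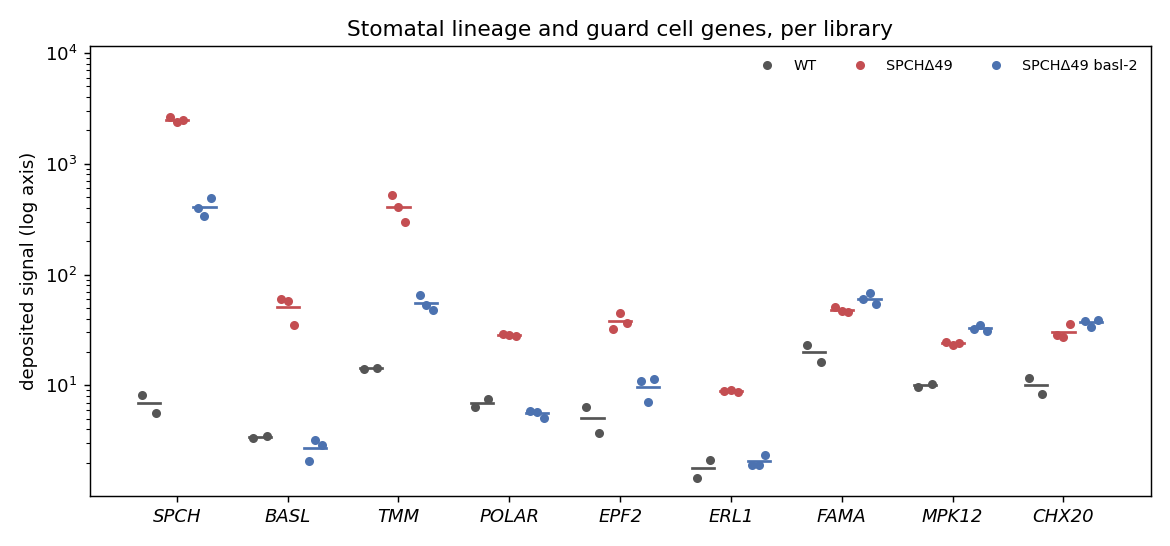
Deposited signal (log axis) of 9 stomatal lineage and guard cell genes, with 1 point per library and a line at each group's mean (n = 2 for WT, n = 3 for the others). BASL, POLAR and ERL1 lie far above WT in SPCHΔ49 and near WT in SPCHΔ49 basl-2, while FAMA, MPK12 and CHX20 are higher in both overexpressors than in WT.

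In SPCHΔ49, 16 of 31 listed regulators of the stomatal lineage, SPCH itself among them, were more abundant than in WT, in libraries in which root markers had a median of 1.1% of their WT level. TMM (AT1G80080), a receptor-like protein that restricts stomatal patterning, rose from 14.3 ± 0.236 (n = 2) to 408.3 ± 113 (n = 3), a log2 fold change of 4.71. The secreted peptide EPF2 (AT1G34245), which limits entry into the lineage, rose from 5.07 ± 1.91 to 37.8 ± 6.26, and the receptor kinase ERL1 (AT5G62230) from 1.78 ± 0.451 to 8.87 ± 0.204. SCRM (AT3G26744), the dimerization partner of SPCH, rose from 44.5 ± 1.85 to 210.5 ± 43.6, and the polarity protein gene POLAR (AT4G31805) from 6.99 ± 0.866 to 28.5 ± 0.526. Beside these 16, 1 fell, and the counts were 17 and 1 adjusted over the list alone and 18 and 0 after quantile normalization. Without SPCH and BASL 14 of 29 rose and 1 fell, with an adjusted p of 1.43e-07 and an adjusted p = 0.0516 with an estimated correlation. The list's median log2 fold change was 0.74, with an adjusted p of 3.14e-09 in limma's camera test and an adjusted p = 0.0512 with an estimated correlation. Besides those named, SCRM2, HDG2, SOL1 (AT3G22760), TCX2, ERL2 and FAMA rose, with log2 fold changes of 1.96, 1.51, 2.22, 1.94, 1.46 and 1.25. MUTE and SCAP1 rose by 0.90 and 0.74, and BRXL2 by 0.73. MYB88, which acts with FLP at the last division of the lineage, fell by 0.68 on the log2 scale. These 4 calls depended on the WT libraries: without WT replicate 1 the adjusted p was 0.0648 for MUTE, 0.068 for SCAP1, 0.285 for BRXL2 and 0.0689 for MYB88, and without WT replicate 2 it was 0.0635, 0.0789, 0.075 and 0.166. BRXL2 also lost its call without SPCHΔ49 replicate 1 (0.109), SPCHΔ49 replicate 2 (0.126) or SPCHΔ49 basl-2 replicate 1 (0.0743), and MYB88 under quantile normalization (0.081).

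Of 26 genes of guard cell function 11 rose and 1 fell in SPCHΔ49, or 15 and 1 adjusted over the list alone, in the same libraries with low root markers. After quantile normalization 17 were up and 0 down, and after the rescaling 16 and 1. MPK12 (AT2G46070), a guard cell MAP kinase, rose from 9.99 ± 0.521 (n = 2) to 23.9 ± 0.812 (n = 3), and the guard cell transcription factor MYB60 (AT1G08810) from 10.8 ± 2.28 to 36.4 ± 5.86. For this list camera gave an adjusted p of 1.15e-05, and the adjusted p = 0.143 with an estimated correlation. The gene that fell, MYB61 (AT1G09540), had a signal of only 1.09 ± 0.073 in WT and 0.227 ± 0.173 in SPCHΔ49. Its sign was not stable, since the log2 fold change was -0.77 as deposited and 0.039 after quantile normalization.

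Outside the fixed lists, SWEET1 (AT1G21460), a sugar transporter, rose from 9.36 ± 1.57 (n = 2) to 263.9 ± 103 (n = 3). The uncharacterized gene AT1G12845 rose by 4.34, ETC3 (AT4G01060), a single-repeat MYB of epidermal patterning, by 4.13, IAN6 (AT1G33930) by 4.04, the uncharacterized AT1G79170 by 4.01 and the receptor-like kinase gene CRK4 (AT3G45860) by 4.16. AT3G51020 was listed at 0 in both WT libraries and had 13.1, 18.8 and 15.3 in SPCHΔ49. MBS1 (AT3G02790) was listed at 0 in both WT libraries and had 24.0, 22.8 and 18.0 in SPCHΔ49, and its adjusted p of 0.0222 became 0.132 and 0.129 without WT replicates 1 and 2, 0.0599 without SPCHΔ49 replicate 1 and 0.0649 without SPCHΔ49 replicate 2.

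Of 14 root markers 10 had less than 10% of their WT level in both overexpressors, although the labels give whole seedlings for every sample. TIP2;3 (AT5G47450), a tonoplast aquaporin of roots, had 71.4 ± 0.263 in WT (n = 2), 0.106 ± 0.033 in SPCHΔ49 (n = 3) and 0.406 ± 0.385 in SPCHΔ49 basl-2 (n = 3). PRP3 (AT3G62680), a root hair wall protein, had 19.0 ± 2.14, 0.215 ± 0.0848 and 0.551 ± 0.428. The phosphate exporter PHO1 (AT3G23430) had 25.6 ± 0.705, 5.20 ± 0.691 and 6.69 ± 1.17. The root hair expansin EXPA18 (AT1G62980) had 6.54 and 6.93 in WT and was listed at 0 in all 6 overexpressor libraries. EXPA7 (AT1G12560) had 8.11 and 9.40 in WT and was listed at 0 in all of them but SPCHΔ49 basl-2 replicate 3, with 0.0725. CASP1 (AT2G36100), a Casparian strip protein, had 41.2 and 48.8 in WT, 0.519, 0.197 and 0.126 in SPCHΔ49, and 0, 0.174 and 0.472 in SPCHΔ49 basl-2. Of 14 listed root markers 11 fell in SPCHΔ49 and 12 in SPCHΔ49 basl-2, none rose, and 11 and 13 fell when adjusted over the list alone. Camera adjusted p-values were 1.50e-10 and 1.01e-09, with an adjusted p = 0.0932 and an adjusted p = 0.216 with an estimated correlation. SCR, which is also expressed in shoots, had log2 fold changes of -0.09 and -0.18 that did not pass. SHR (AT4G37650) had 13.8 ± 1.31, 10.7 ± 1.42 and 7.75 ± 0.853, passing only in SPCHΔ49 basl-2. The phosphate transporter PHT1;1 (AT5G43350) had 38.2 ± 6.93, 10.6 ± 9.05 and 8.10 ± 6.69, passing in neither, with 20.3 in SPCHΔ49 replicate 3.

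**Figure D2:**
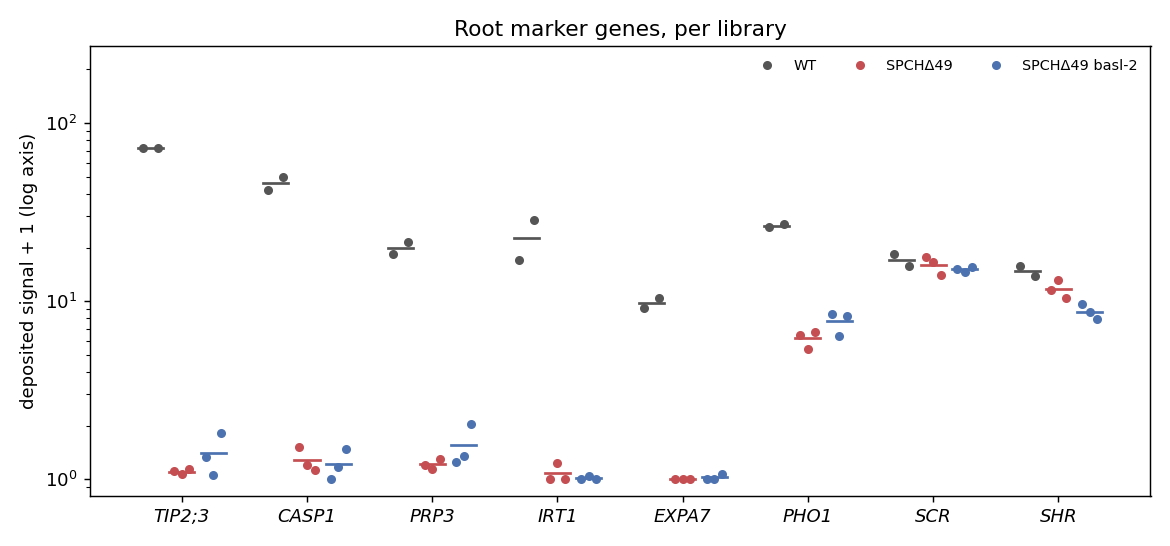
Deposited signal + 1 (log axis) of 8 root marker genes, with 1 point per library and a line at each group's mean (n = 2 for WT, n = 3 for the others). TIP2;3, CASP1, PRP3, IRT1 and EXPA7 sit near 1, that is near a signal of 0, in all 6 overexpressor libraries, while SCR is at a similar level in the 3 genotypes.

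The largest decreases in SPCHΔ49 included AT2G05510, a glycine-rich protein gene, with a log2 fold change of -7.27, the extensin-like gene AT3G28550 with -6.16, TIP2;3 with -6.03, and CYP81F4 (AT4G37410), of indole glucosinolate modification, with -5.83. TPS27 (AT3G25820), a root cineole synthase with a near-identical copy, had -5.73. AIR1 (AT4G12550) had 84.7 and 61.6 in WT and 0, 0.281 and 0.419 in SPCHΔ49. The major-latex-protein-like genes MLP328, MLP34 and MLP329 had log2 fold changes of -6.41, -6.28 and -6.26, and are near-identical relatives among which reads may be divided uncertainly. The drought-repressed gene ATDR4 (AT1G73330) fell by 6.13. Without WT replicate 1 the adjusted p was 0.0655 for MLP328, 0.0872 for MLP34 and 0.11 for ATDR4, and without WT replicate 2 it was 0.0588, 0.0837 and 0.102, with 0.0519 for ATDR4 without SPCHΔ49 replicate 2.

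The vascular, photosynthesis, flavonoid and glucosinolate lists passed camera in SPCHΔ49 against WT, pointing down, the flavonoid and glucosinolate lists by a narrow margin. Of 14 vascular markers 10 fell and none rose (12 adjusted over the list alone), among them the procambial transcription factor gene ATHB8 (AT4G32880), from 14.2 ± 0.0488 (n = 2) to 6.63 ± 0.368 (n = 3), and the xylem protease gene XCP2 (AT1G20850), from 55.6 ± 0.961 to 20.8 ± 3.15. Vascular markers had a camera adjusted p of 0.000106, with an adjusted p = 0.143 with an estimated correlation. Of 25 photosynthesis genes 11 fell and none rose, the same number adjusted over the list alone, including SBPASE (AT3G55800) and GAPB (AT1G42970) of the Calvin cycle, with log2 fold changes of -1.30 and -1.23. Their camera adjusted p was 0.000587, with an adjusted p = 0.561 with an estimated correlation. Of 12 flavonoid genes 7 fell and 1 rose (8 and 1 adjusted over the list alone), with F3H (AT3G51240) down from 26.7 ± 2.64 to 4.88 ± 0.523 and LDOX (AT4G22880) from 7.57 ± 4.27 to 0.161 ± 0.0659. The camera adjusted p was 0.0185, an adjusted p = 0.526 with an estimated correlation, and it was 0.0813 without WT replicate 1 and 0.129 without WT replicate 2. Of 20 glucosinolate genes 4 fell and none rose (1 adjusted over the list alone, 2 after the rescaling), with CYP79B3 (AT2G22330), which starts indole glucosinolate synthesis, down from 100.1 ± 0.0124 to 30.2 ± 5.91. In camera the glucosinolate list had an adjusted p of 0.04, which became an adjusted p = 0.682 with an estimated correlation, 0.222 in limma's fry and 0.149 without SPCHΔ49 replicate 1. The vascular, flavonoid and glucosinolate results accompanied the low root markers given above. The photosynthesis list holds leaf mesophyll genes, whose share of the signal less root tissue alone would raise. Their decrease is therefore not what less root tissue alone would give.

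The cell cycle and salicylic acid lists passed camera in SPCHΔ49 pointing up, also by a narrow margin. Of 35 cell cycle genes 5 rose and 2 fell (3 and 2 adjusted over the list alone, and 8 and 2 after quantile normalization or the rescaling), with CYCD3;1 (AT4G34160), a D-type cyclin, up from 18.8 ± 2.16 (n = 2) to 40.1 ± 7.06 (n = 3). This list's camera adjusted p was 0.0341, an adjusted p = 0.64 with an estimated correlation, 0.401 without WT replicate 1, 0.141 without SPCHΔ49 replicate 3, 0.0748 under the rescaling, 0.261 in fry and 0.102 with the replicate block. CYCD3;1 itself had an adjusted p of 0.0562 without WT replicate 1. Of 14 salicylic acid genes 1 rose as deposited and 5 after quantile normalization, and 1 adjusted over the list alone. As deposited this was CBP60G (AT5G26920), a regulator of salicylic acid synthesis, from 2.48 ± 0.983 to 21.6 ± 11.9. Its adjusted p was 0.0728 without WT replicate 1 and 0.115 without WT replicate 2. The list's adjusted p was 0.0173, an adjusted p = 0.64 with an estimated correlation, 0.0819 without WT replicate 2, 0.0666 without SPCHΔ49 replicate 3, 0.0983 under the rescaling, 0.239 in fry and 0.0587 with the replicate block. Single libraries differed widely, since PR1 (AT2G14610) had 0.549 and 0.0951 in WT, 3.72, 59.6 and 158 in SPCHΔ49, and 31.4, 0 and 79.3 in SPCHΔ49 basl-2.

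The other 11 lists did not pass camera in SPCHΔ49 against WT, and their members went up or down as follows. In trichome development 0 rose and 2 of 11 fell (CPC and TTG2), with adjusted p of 0.055 and 0.0916 without WT replicate 1 and 0.0621 and 0.107 without WT replicate 2, and TTG2 with 0.151 under quantile normalization. In cuticle and epidermal wax 2 of 15 rose and 3 fell, with a median of 0.23, a mean of -0.01 and a test pointing up. In abscisic acid and dehydration response 4 of 18 fell, among them RD22 (AT5G25610), from 490.6 ± 52.7 (n = 2) to 36.4 ± 10.7 (n = 3). This list passed camera without SPCHΔ49 replicate 3 (adjusted p 0.00471), under quantile normalization (0.0385), under the rescaling (0.0291) and with the replicate block (0.0334). It also passed without WT replicate 1, which left only WT replicate 2. Every listed member was higher in WT replicate 2 than in WT replicate 1, such as RD29B with 73.0 against 10.6 and HAI1 with 97.4 against 12.5. In jasmonate and ethylene defence 5 of 21 fell, and this list passed with the replicate block (0.0307). In auxin response 2 of 10 fell, in brassinosteroid synthesis 1 of 9 rose and 1 fell, and in cell wall loosening 3 of 13 rose and 3 fell. Of 13 clock genes 3 rose and 3 fell, with the evening complex gene ELF3 (AT2G25930) up from 13.0 ± 0.855 to 25.6 ± 2.15. Of 2 seed storage genes 1 fell, with an adjusted p of 0.0375 for the list under the rescaling, and 0 of 4 senescence genes changed. Of 8 reference genes 4 fell and none rose as deposited, while 1 fell after quantile normalization and 2 after the rescaling. ACT8 (AT1G49240) fell from 223.9 ± 9.82 to 148.0 ± 4.12 under every scaling tried, with an adjusted p of 0.0637 without WT replicate 2. Over the list alone the counts of these 11 lists differed only in cell wall loosening, with 3 up and 5 down, in the clock, with 5 up and 3 down, and in seed storage, with 2 down. Without WT replicate 1 trichome development also passed (0.0485). In fry, which tests a list on its own, trichome development (0.00725), auxin (0.0178), seed storage (0.00633) and reference genes (0.000892) passed, all pointing down.

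In all, 5120 genes changed in SPCHΔ49 against WT in limma at an adjusted p under 0.05, 1867 up and 3253 down, and 2055 of them by at least 2-fold, 504 up and 1551 down. The balance of directions followed the scaling, with 36.5% of the changed genes up as deposited, 50.7% after quantile normalization and 61.0% after rescaling without SPCH, organelle and abundant genes, which moved the median of all genes to 0.15 from -0.01. The count was 1121 without WT replicate 1, 1136 without WT replicate 2 and 3198 without SPCHΔ49 replicate 2, and it was 4336 without the 583 genes whose WT mean was over 10 times both overexpressor means.

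**Figure D3:**
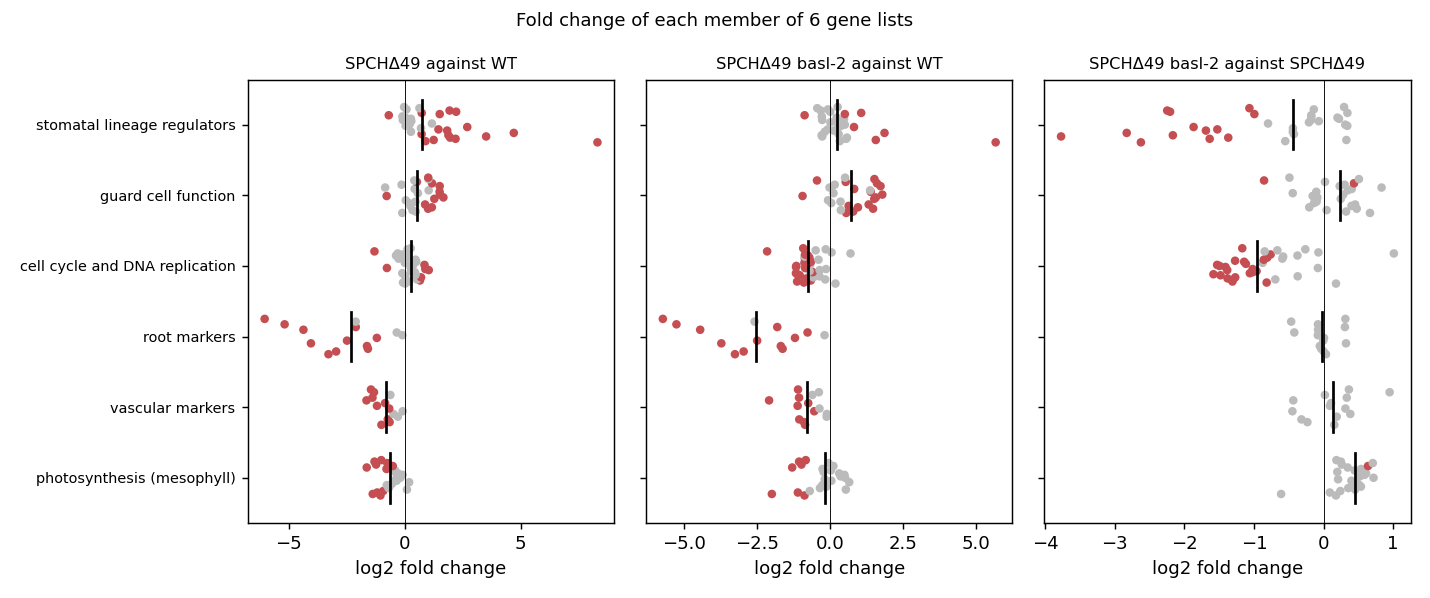
Log2 fold change (horizontal axis, log2(signal + 1) scale) of each member of 6 fixed gene lists in the 3 comparisons, with 1 point per gene, red where the adjusted p was under 0.05 and grey elsewhere, and a black bar at the list's median. The lineage list has a median of 0.74 in SPCHΔ49 and 0.27 in SPCHΔ49 basl-2 against WT, while the cell cycle list has a median of -0.96 in SPCHΔ49 basl-2 against SPCHΔ49.

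In SPCHΔ49 basl-2 against WT, 15 of 26 guard cell genes rose and 2 fell, in libraries in which root markers had a median of 0.963% of their WT level. The numbers were the same adjusted over the list alone and 17 and 0 after quantile normalization, with a median log2 fold change of 0.73. MPK12 rose from 9.99 ± 0.521 (n = 2) to 32.8 ± 1.89 (n = 3), and CHX20 (AT3G53720), a guard cell cation exchanger, from 10.02 ± 2.37 to 37.1 ± 2.74. MYB61 and GHR1 fell, with log2 fold changes of -0.93 and -0.44. The guard cell adjusted p in camera was 3.31e-06, and the adjusted p = 0.216 with an estimated correlation. Of 31 lineage regulators 6, SPCH among them, rose and 1 fell (5 and 1 adjusted over the list alone, 9 and 0 after quantile normalization). FAMA (AT3G24140), which acts at the last step before guard cells form, rose from 19.8 ± 4.84 to 60.6 ± 6.53, TMM from 14.3 ± 0.236 to 55.5 ± 8.58, and SCAP1 (AT5G65590), a Dof factor of guard cell maturation, from 5.44 ± 0.206 to 12.6 ± 1.03. HDG2 and EPF2 rose by 0.52 and 0.83, and MYB88 fell by 0.86 on the log2 scale. The lineage list's camera adjusted p was 0.0221, an adjusted p = 0.306 with an estimated correlation and 0.0597 under the rescaling, which leaves out SPCH. Without SPCH and BASL it was 0.0439, with an adjusted p = 0.317 with an estimated correlation. Without WT replicate 2 the adjusted p was 0.0707 for HDG2, 0.0763 for MYB88 and 0.292 for EPF2. EPF2 also lost its call without WT replicate 1 (0.0617), each SPCHΔ49 replicate (0.0577, 0.0651 and 0.0647) and SPCHΔ49 basl-2 replicates 1 and 3 (0.126 and 0.095). GHR1 lost its call without any library but SPCHΔ49 basl-2 replicate 3, with an adjusted p of up to 0.179 without either WT replicate. Under quantile normalization the adjusted p was 0.843 for MYB61, 0.066 for MYB88 and 0.303 for GHR1.

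Of 35 cell cycle genes 21 fell in SPCHΔ49 basl-2 against WT and none rose (25 down and 1 up adjusted over the list alone, 13 down and 1 up after quantile normalization, 17 down after the rescaling), with a median log2 fold change of -0.75. TSO2 (AT3G27060), a small subunit of ribonucleotide reductase, fell from 46.0 ± 9.17 (n = 2) to 9.81 ± 3.08 (n = 3). It also fell in SPCHΔ49, to 18.4 ± 5.51 (n = 3), and did not pass between the overexpressors (limma adjusted p of 0.134). The cell cycle list's camera adjusted p was 0.000266, and the adjusted p = 0.508 with an estimated correlation. Of 14 vascular markers 9 fell and none rose, the same adjusted over the list alone, with the cambial receptor kinase gene PXY (AT5G61480) down from 12.4 ± 1.15 to 6.30 ± 0.682. The vascular adjusted p was 0.00247, and the adjusted p = 0.306 with an estimated correlation. Of 20 glucosinolate genes 7 fell and none rose, also over the list alone, with CYP79B3 down to 22.5 ± 4.57. The list's camera adjusted p was 0.0104, an adjusted p = 0.764 with an estimated correlation and 0.0839 in fry. Of 12 flavonoid genes 7 fell and 2 rose, also over the list alone, with F3H down to 5.65 ± 0.91. Their camera adjusted p was 0.0292, an adjusted p = 0.508 with an estimated correlation, 0.107 without WT replicate 1 and 0.237 without WT replicate 2. These results accompanied the low root markers given above.

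The largest increases in SPCHΔ49 basl-2 against WT, after SPCH, included enzymes of amino acid breakdown. THA1 (AT1G08630), a threonine aldolase, rose from 9.08 ± 2.02 (n = 2) to 254.5 ± 88.6 (n = 3), and BCAT2 (AT1G10070), a branched-chain amino acid transaminase, from 13.5 ± 0.848 to 276.4 ± 57.2. XTH25 (AT5G57550), a wall-modifying enzyme, rose from 3.53 ± 1.92 to 48.6 ± 5.56, and the uncharacterized AT2G41105 from 0.865 ± 0.396 to 32.9 ± 17.5. XTH15 and XTH22 rose by 4.26 and 3.46, with an adjusted p of 0.0586 for XTH15 without WT replicate 1 and of 0.0605 and 0.059 for XTH15 and XTH22 without WT replicate 2. AT2G05510, MLP329, CYP81F4 and TIP2;3 were among the largest decreases, with log2 fold changes of -7.69, -5.87, -5.84 and -5.72, and kept their calls whichever library was left out. Other large decreases did not. MLP34 and RDL5 (AT4G11320), a papain-type protease, had log2 fold changes of -6.78 and -5.88, with adjusted p of 0.0613 and 0.0615 without WT replicate 1 and 0.0593 and 0.0619 without WT replicate 2. The glycine-rich protein gene ATGRP9 (AT2G05440) had 1814 and 2691 in WT and 0, 8.13 and 121.9 in SPCHΔ49 basl-2, with adjusted p of 0.112 and 0.125 without WT replicates 1 and 2 and 0.0504 without SPCHΔ49 basl-2 replicate 2. MLP328 had 370.4 and 323.8 in WT and 0, 3.08 and 15.1 in SPCHΔ49 basl-2, with an adjusted p of 0.0538 without WT replicate 1.

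The other 13 lists did not pass camera in SPCHΔ49 basl-2 against WT. Of 25 photosynthesis genes 7 fell and none rose, with RBCS1B (AT5G38430), whose near-identical relatives make its level uncertain, down from 1758 ± 275 (n = 2) to 455.9 ± 136 (n = 3), and the list had an adjusted p of 0.4 as deposited. After quantile normalization 9 fell and 4 rose, and the list's adjusted p was 0.0372. In trichome development 1 of 11 rose and 3 fell, in cuticle and wax 0 of 15 rose and 4 fell, in abscisic acid response 5 of 18 fell, in salicylic acid defence 1 of 14 rose, and in jasmonate defence 1 of 21 rose and 5 fell. In auxin response 1 of 10 rose and 2 fell, in brassinosteroid synthesis 3 of 9 rose, and in cell wall loosening 3 of 13 rose and 2 fell. Of 13 clock genes 3 rose and 2 fell, both seed storage genes fell, 1 of 4 senescence genes rose and 2 of 8 reference genes fell. The seed storage gene CRA1 (AT5G44120) had 86.5 and 1.85 in WT and a limma adjusted p of 0.0445. That became 0.087 with a pseudocount of 5, 0.0767 under quantile normalization and 0.0529 with the replicate block. Over the list alone 4 fell in abscisic acid response and 3 in cell wall loosening, and the other counts were equal. Median, mean and test differed in sign for cuticle and wax (0.04, -0.19 and down) and for cell wall loosening (-0.54, 0.23 and down). Without WT replicate 1 the abscisic acid and salicylic acid lists passed. For abscisic acid this left only WT replicate 2, in which every listed member was higher than in WT replicate 1. The salicylic acid list also passed camera without SPCHΔ49 basl-2 replicate 2 (adjusted p 0.00111). Abscisic acid response also passed under quantile normalization (0.0289) and with the replicate block (0.0423), and jasmonate defence with the block (0.0323). In fry trichome development (0.0204), the clock (0.0371), seed storage (0.00544) and reference genes (0.0144) passed. Under quantile normalization the medians of the trichome, cuticle and reference lists changed sign, to 0.06, -0.01 and 0.03.

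In SPCHΔ49 basl-2 against WT 6458 genes changed in limma, 2382 up and 4076 down, and 2328 by at least 2-fold, 629 up and 1699 down. As deposited 36.9% of them were up, against 49.0% after quantile normalization. The count was 1624 and 1752 without WT replicates 1 and 2, and 5705 without the 583 genes at the level of the root markers.

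Between the overexpressors, 13 of 31 lineage regulators, SPCH and BASL among them, fell with basl-2 and none rose (15 adjusted over the list alone), with a median log2 fold change of -0.44. POLAR fell from 28.5 ± 0.526 (n = 3) in SPCHΔ49 to 5.59 ± 0.453 (n = 3) in SPCHΔ49 basl-2, TMM from 408.3 ± 113 to 55.5 ± 8.58, ERL1 from 8.87 ± 0.204 to 2.06 ± 0.252, and SPCH itself from 2491 ± 136 to 407.2 ± 74.9. BASL, TCX2, SOL1, HDG2, ERL2 and SCRM fell too, with log2 fold changes of -3.77, -2.25, -2.21, -0.99, -1.53 and -1.64. The camera adjusted p was 1.63e-08, and the adjusted p = 0.0616 with an estimated correlation. Without SPCH and BASL 11 of 29 fell, with an adjusted p of 1.44e-06 and an adjusted p = 0.0715 with an estimated correlation. EPF2, SCRM2 and SMR4 had log2 fold changes of -1.87, -1.37 and -1.07, with adjusted p of 0.057, 0.109 and 0.124 without SPCHΔ49 replicate 2. SCRM2 also lost its call without WT replicates 1 and 2 (0.051 and 0.0511), SPCHΔ49 replicate 1 (0.0509) and SPCHΔ49 basl-2 replicate 1 (0.078), and SMR4 without SPCHΔ49 replicate 1 (0.0694), SPCHΔ49 basl-2 replicates 1 and 2 (0.109 and 0.0512) and under quantile normalization (0.107). Of 26 guard cell genes 1 rose and 1 fell (2 and 1 adjusted over the list alone), with a median of 0.24 (0.099 after quantile normalization and 0.084 after the rescaling) and a camera adjusted p of 0.137. FAMA had a log2 fold change of 0.33 and an adjusted p of 0.233. SPCH itself differed between these lines. Differences given as with basl-2, here and below, can therefore not be assigned to basl-2 rather than to the level of SPCH.

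Of 35 cell cycle genes 22 fell with basl-2 and none rose (28 down and 1 up adjusted over the list alone, 18 down after quantile normalization), with a median log2 fold change of -0.96. CYCD3;1 fell from 40.1 ± 7.06 (n = 3) to 14.6 ± 1.22 (n = 3), and the A-type cyclin gene CYCA1;1 (AT1G44110) from 9.97 ± 0.553 to 3.27 ± 0.897, the latter with an adjusted p of 0.0597 without SPCHΔ49 replicate 2. Camera gave an adjusted p of 9.12e-16, and the adjusted p = 0.295 with an estimated correlation. The protodermal gene PDF1 (AT2G42840) fell by 1.09 on the log2 scale, with an adjusted p of 0.057 without SPCHΔ49 replicate 2. Outside the lists, ETC3 fell from 178.9 ± 28.3 to 28.4 ± 6.42, IAN6 from 35.8 ± 6.86 to 3.67 ± 0.648, AT1G12845 from 163.6 ± 9.49 to 20.7 ± 3.86, AT5G10890 from 37.6 ± 11.6 to 3.41 ± 0.673 and ATMYC1 (AT4G00480) from 41.8 ± 16.4 to 6.10 ± 0.459.

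The photosynthesis and auxin lists passed camera with basl-2, pointing up, with few members past the threshold. Of 25 photosynthesis genes 1 rose and none fell, also over the list alone, with a median of 0.45, a camera adjusted p of 2.14e-05 and an adjusted p = 0.698 with an estimated correlation. Quantile normalization gave an adjusted p of 0.731 and a median of 0.028, and fry gave 0.196. The gene that rose, GAPA (AT3G26650) of the Calvin cycle, lost its call under quantile normalization (0.193), without WT replicates 1 and 2 (0.0672 and 0.0674), SPCHΔ49 replicates 2 and 3 (0.148 and 0.0941) and SPCHΔ49 basl-2 replicates 1 and 2 (0.124 and 0.0654). Of 10 auxin genes 2 rose and none fell (3 adjusted over the list alone), with a median of 0.65, a camera adjusted p of 0.00498 and an adjusted p = 0.295 with an estimated correlation. The auxin genes that rose were GH3.5 (AT4G27260), an auxin-conjugating enzyme, from 28.2 ± 5.45 (n = 3) to 57.1 ± 3.39 (n = 3), and the auxin carrier gene PIN7 (AT1G23080), from 26.3 ± 4.67 to 61.8 ± 17.1. For GH3.5 the adjusted p was 0.0515, 0.0775, 0.0792 and 0.0576 without SPCHΔ49 replicates 1 and 2 and SPCHΔ49 basl-2 replicates 1 and 2. PIN7 lost its call without any library but SPCHΔ49 basl-2 replicate 3, with an adjusted p of up to 0.132 without SPCHΔ49 basl-2 replicate 1. Among the largest increases, MSRB6 (AT4G04840), a methionine sulfoxide reductase, rose from 1.60 ± 0.975 to 35.9 ± 3.92, the desaturase gene ADS1 (AT1G06080) from 0.848 ± 0.0169 to 17.1 ± 4.36, the uncharacterized AT5G57760 from 0.569 ± 0.616 to 11.4 ± 5.14, and THA1 from 35.3 ± 7.6 to 254.5 ± 88.6.

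The remaining 15 lists did not pass camera between the overexpressors. In trichome development 1 of 11 fell (4 up and 3 down adjusted over the list alone) and in cuticle and wax 1 of 15 fell (2 over the list alone). No member changed over all genes in the root, vascular, abscisic acid, salicylic acid, jasmonate, glucosinolate, flavonoid, brassinosteroid, cell wall, clock, seed storage, senescence and reference lists, and 2 reference genes were up over the list alone. In limma 4120 genes had an unadjusted p under 0.05 in this comparison, and by fry the reference list had an adjusted p of 0.015. Median, mean and test differed in sign for root markers (-0.02, -0.02 and up), abscisic acid response (-0.06, -0.12 and up), flavonoids (0.13, -0.00 and up) and senescence (-0.14, 0.16 and up). Without SPCHΔ49 replicate 1 the guard cell list, pointing up, and the salicylic acid list had an adjusted p of 0.0445, and the glucosinolate list of 0.0182. Abscisic acid response passed without SPCHΔ49 replicate 3 (0.029), cell wall loosening without SPCHΔ49 basl-2 replicate 1 (0.0385), jasmonate defence without replicate 2 of that line (0.0029) and glucosinolates without its replicate 3 (0.000313). Under the rescaling cell wall loosening (0.0155) and jasmonate defence (0.049) passed, under quantile normalization cuticle and wax (0.0391), and with the replicate block glucosinolates (0.0291). The median of abscisic acid response was 0.01 after quantile normalization and those of the clock and reference lists were -0.01 and -0.07 after the rescaling, each with the sign opposite to the deposited values.

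In all, 1020 genes differed between SPCHΔ49 basl-2 and SPCHΔ49 in limma, 387 up and 633 down, and 393 by at least 2-fold, 152 up and 241 down. As deposited 37.9% were up, against 16.5% after rescaling, which moved the median of all genes to -0.17 from -0.03. The count was 498 without either WT replicate, 620, 151 and 426 without SPCHΔ49 replicates 1, 2 and 3, and 237 and 421 without SPCHΔ49 basl-2 replicates 1 and 2.

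The changes against WT were largely held in common by the overexpressors. Of the genes called in SPCHΔ49, 1202 rose and 2686 fell in SPCHΔ49 basl-2 too, 3888 in total, where independent lists of these sizes would share 236 and 703, and 23 were called in opposite directions. In simulations of unchanged groups, 0.01 calls were shared on average over 100 draws. The WT samples were drawn anew too, and each gene was drawn independently. The simulation thus leaves out variation common to many genes and any trait of the actual WT libraries. It is no measure of what those libraries alone would make the comparisons share. The covariance of the fold changes across genes was 0.642 against 0.0589 in the simulation, their correlation 0.884 against 0.600, and 82.2% of genes had the same sign against 70.5%, where genes are not independent replicates. Of the 1867 genes that rose in SPCHΔ49, 237 were significantly lower again with basl-2 (12.7%), TMM, ERL1, POLAR and ETC3 among them. Another 50 of them rose significantly further. Of the 3253 that fell 148 were significantly higher (4.55%), and 35 fell further. These genes were selected through the same SPCHΔ49 libraries that basl-2 is compared with, which by itself favours a move back. The 2 WT libraries cannot be split into groups of 2, so part of the excess may come from the shared controls. With only 1 WT library the overlap was smaller. Fewer genes were then called in each comparison, so this does not show how much the shared controls contribute. The overlap was 3185 without the 583 genes at the level of the root markers. Genes lowered less were kept in that count, so it cannot show how much of the overlap root content accounts for.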

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

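The tests of the stomatal lineage explanations were chosen only after the values they measure were seen. The tests of root tissue and root hairs, with their gene lists, were chosen after the root pattern was seen but before the values of the added genes were, and only the other splits of the samples were planned. Groups of 2 or 3 samples were not tested for outliers.

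Apart from the root markers, the results given here were picked out because the overexpressors differed from each other in their change from WT, by a direct test. The root markers were taken up for their low level in both overexpressors, and none of them passed the threshold between these lines. SPCHΔ49 basl-2 and SPCHΔ49 differed in 1020 genes, while the highest count of the other 9 splits of the 6 libraries was 0. Each of the other 9 splits placed libraries of both lines in each group. The difference between the lines then added to the spread within groups, which lowers the count. Their count of 0 therefore does not show how many genes would be called without a difference between the lines. With 10 splits in all, of which 1 gave as many genes, a share under 0.05 cannot be reached. Lists that differed were stomatal lineage regulators (median log2 difference -0.44), cell cycle (-0.96), photosynthesis (0.45) and auxin (0.65). None of the 4 passed with an estimated correlation, with adjusted p of 0.0616, 0.295, 0.698 and 0.295. The photosynthesis list also did not pass under quantile normalization, with a median of 0.028 and a camera adjusted p of 0.731, or in fry (0.196).

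Of 31 lineage regulators 13, SPCH and BASL included, fell with basl-2 and 0 rose. Whether there were far fewer stomatal and guard cells altogether was looked at through the median log2 difference of the guard cell list. It was 0.24 as deposited, 0.099 after quantile normalization and 0.084 after the rescaling. At 2 standard errors below it was 0.05, -0.096 and -0.11. These standard errors were taken across the 26 genes, which are not independent replicates, and do not measure the spread between libraries. Guard cell transcripts were thus not lower on balance by the median. This test was chosen after the median was seen, and a relative signal does not count cells. A decrease in guard cells, small or large, is therefore not excluded. A lower level of the SPCH transgene may account for the decrease of the lineage regulators, as SPCH had a log2 difference of -2.62. It cannot be told apart from an effect of basl-2 itself, because each genotype is represented by 1 line. The same holds for the cell cycle, photosynthesis and auxin lists and for the other genes that differed between these lines. The biological explanation in the design, loss of BASL, therefore stays open and untested.

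Of 14 root markers 10 had under 10% of their WT level in both overexpressors, with list medians of 1.1% of WT in SPCHΔ49 and 0.963% in SPCHΔ49 basl-2. Loss of root hair cells alone is argued against, since 11 added endodermis and suberin genes had a median of 2.13% of WT in SPCHΔ49 and 1.56% in SPCHΔ49 basl-2, with CASP2 (AT3G11550) the exception at 94.4% in SPCHΔ49 basl-2 (12.9, 15.8 and 3.59 against 10.9 and 11.8 in WT). Little or no root tissue in the overexpressor samples may explain the pattern: over both added root lists the medians were 6.80% and 2.96% of WT. The 8 stele and transport genes had medians of 19.0% and 10.9%, with 1 of them at 110.2% and 149.7%, and some stele genes are also expressed in shoots. Whether roots were small, absent or not collected was not tested, and an effect of the SPCHΔ49 genotype on root growth stays open.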

How the results depend on the processing

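The covariate for salicylic acid genes, the removal of genes at the level of root markers, TMM scaling for list tests and the lineage list without SPCH and BASL were chosen only after the data were seen. The totals given next pool alternatives that moved no named gene, such as no filter, with the leaving out of single libraries. Without SPCHΔ49 replicate 2, for example, 34 of 191 values of named genes lost the call. Over all alternatives, 3634 values of named genes kept their side of the threshold, 275 lost the call, 1 gained it and 1 reversed. For list tests these numbers were 819 kept, 40 lost and 35 gained, and of the counts 100 stayed within 1.5 times with the same direction in the majority, and 32 did not. The first comparison's counts under quantile normalization and the rescaling are among the 32 only because most genes were then up. The cause of the changes below was not tested, except where fewer samples or a stricter criterion explain them.

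In the order SPCHΔ49 against WT, SPCHΔ49 basl-2 against WT and SPCHΔ49 basl-2 against SPCHΔ49, with 5120, 6458 and 1020 genes as deposited, leaving out 1 library gave 1121 to 5636, 1624 to 7052 and 151 to 1242 genes. The overlap of 3888 then ranged from 787 to 4125. The lowest counts came without WT replicate 1 against WT, and without SPCHΔ49 replicate 2 between the overexpressors. Where a WT library was left out, the other was assumed to vary like the other groups, and the seed storage list had no value.

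Quantile normalization gave 5488, 6385 and 754 genes, with 50.7% up in the first comparison, and turned MYB61 (AT1G09540) in SPCHΔ49 against WT from -0.77 to 0.039. The rescaling without SPCH, organelle and abundant genes gave 6151 and 1788 genes in the first and last comparison, and no value for SPCH, which it leaves out. A model of only the 2 groups compared gave 485 in the last. A fold of at least 2 left 2055, 2328 and 393. Sample quality weights gave 11119, 12325 and 15152 genes, an overlap of 8409 and a log2 fold change of -0.51 for BASL in SPCHΔ49 basl-2 against WT. Their fit did not converge, and SPCHΔ49 replicate 2 and SPCHΔ49 basl-2 replicate 1 had weights of 33.9 and 25.1. The salicylic acid covariate gave 7726 and 1789 in the first and last comparison and an overlap of 6423. A filter of 5 gave 3944, 5112 and 825. No filter moved nothing, since the listed genes all pass the filter.

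The replicate block gave 6446, 8045 and 1494 genes and an overlap of 5146. The numbers do not pair the samples: deviations from the group mean correlated at -0.17, -0.09 and 0.76 between equal numbers of the overexpressors, and at 0.77 between SPCHΔ49 replicate 1 and SPCHΔ49 basl-2 replicate 2. Between SPCHΔ49 replicate 2 and SPCHΔ49 basl-2 replicate 1 the value was 0.33. Variation within the overexpressors was thus partly shared in another order. In a principal component analysis, the second component (21.7% of the variance) spread libraries within each overexpressor. The third (11.3%) separated the 2 lines. The main model has no term for such shared variation.

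Of the lists, 9, 7 and 4 passed camera at the preset correlation. With an estimated correlation 0, 0 and 0 passed (4, 2 and 3 at an unadjusted p under 0.05), and with fry 10, 10 and 4. Leaving out 1 library gave 7 to 9, 6 to 8 and 4 to 7. The deposited values hold no read numbers, so what depth limits could not be assessed, and count models were not run.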

Other observations

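The list of sugar starvation genes and its test were chosen after THA1 and BCAT2 had been seen, though the test used only members whose values had not been seen. The test of the hour of harvest was chosen after the clock values were seen.

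Dark-inducible genes were higher in SPCHΔ49 basl-2 than in SPCHΔ49. ASN1 (AT3G47340), an asparagine synthetase, rose from 563.6 ± 106 (n = 3) to 2194 ± 493 (n = 3), and 16 of 24 listed starvation genes rose while 0 fell, with a median log2 fold change of 1.48. A sugar starvation response higher in SPCHΔ49 basl-2 may be present: 18 of 18 members not seen before were higher, 10 of them past the threshold, with a camera p of 6.01e-16, and a p of 0.00777 with an estimated correlation. Against WT 19 of 24 rose in SPCHΔ49 basl-2 and 10 in SPCHΔ49, with medians of 1.94 and 0.61. SPCH was also lower in SPCHΔ49 basl-2 than in SPCHΔ49, so an effect of its level cannot be told apart from one of basl-2. A different hour of harvest cannot be told apart, and the labels give no hour. The 6 evening clock genes minus 3 morning genes gave a log2 difference of -0.28, with an SE of 0.13 across genes. That SE does not measure the spread between libraries, so a shift of the clock is neither shown nor excluded.

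Defence genes differed between libraries of 1 genotype, and the 2 given here were chosen after their values were seen. The salicylic acid marker PR2 (AT3G57260) had 2.01 and 0.892 in WT, 14.8, 115.5 and 151 in SPCHΔ49, and 26.0, 0.875 and 76.3 in SPCHΔ49 basl-2. The jasmonate regulator MYC2 (AT1G32640) had 8.07 and 7.57 in WT and was listed at 0 in SPCHΔ49 replicates 1 and 2 and SPCHΔ49 basl-2 replicates 1 and 2, with 22.4 and 25.6 in the replicates numbered 3.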
